A study of Homo sapiens with 6 samples.

How the data were processed

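The series holds 6 RNA-seq libraries of primary human bronchial epithelial cells, 3 exposed to PBS and 3 to NETs, and each library was assigned to its group by its label. The authors deposited 1 table of whole-number counts per gene symbol for all 6 libraries, raw and not normalized as far as the values show, with 25245 symbols and totals of 51290603 to 71981670 counts per library. Per the submitters' processing notes, Bowtie, Cufflinks and DESeq were used with genome build GRCh37, with no role or version given. The counting tool, its gene annotation and its use of strand are not given in the sources used here. Low counts were mostly even (69.1% to 73.3% of the counts from 1 to 20 in each library), so the number of independent fragments behind a count is nearer to the count divided by 2. Per the labels, the treatment protocol of all 6 libraries names only NETs with anakinra, a recombinant interleukin-1 receptor antagonist, and anakinra alone. The groups PBS and NETs were therefore taken from the library titles and the series' design text, and no library titled as an anakinra arm was analysed here. The labels do not say which libraries came from the same subject, nor whether the NETs of 3 unrelated donors were pooled.

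All values were computed from the deposited counts in R 4.3.3. Genes were kept with edgeR 4.0.16's filterByExpr (minimum count 10, minimum total count 15), which left 15730, and libraries were scaled with TMM factors (0.858 to 1.15). The main test was edgeR's quasi-likelihood F test of NETs against PBS on all 6 libraries with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at a false discovery rate of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD of 3 libraries, except the sums over marker lists, which use library totals. Principal components were taken from log2 CPM with a prior count of 2.

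Before the data were examined, 36 gene lists were written from general knowledge of airway epithelium, inflammation and other cell types. Their symbols were matched to the table directly or through synonyms in a RefSeq table of assembly GRCh38.p14, used for names only. Of the table's symbols, 18666 were current, 2723 were found through synonyms and 3856 were not found, and no coordinates are printed because the builds differ. The list genes DEFB4A, DEFB4B, MCIDAS, PIFO, MUC5AC, OCLN and TRBC1 were not matched. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the p-values adjusted over the 32 lists, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone.

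Named genes followed a rule fixed before the data were examined. It took CXCL8, IL1A, IL1B, IL1RN, IL36G, IL6 and CXCL1, then the 8 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap of the groups (4 higher and 1 lower qualified), then, within the 2 to 4 allowed, the 3 members with the smallest p of each list described. Some genes that the rule takes are not reported here. Sex-linked genes (107 symbols, 4 of them tested) stayed in the fits and are left out of every reported level and of the principal components.

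Single values per library were compared with an exact permutation test over all assignments of 3 against 3 libraries, whose smallest two-sided p is 0.1. Counts of 2 libraries differed by far more than sampling noise in every pair (chi-square per degree of freedom 188 or more), so no library was treated as a duplicate of another. A gene without counts in a group was given a floor of 6 counts over the group, which stands for 3 fragments at 2 counts each. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, robust dispersions, a replicate block, other thresholds, and leaving out each library or each replicate number. Chosen after seeing the data were a GC offset per library (a GC value of the longest GENCODE transcript for 90.6% of the tested genes), counts divided by 2 and rounded up, removal of 5 small structural RNAs, removal of PBS replicate 2 with NETs replicate 3, the newer edgeR fit (legacy = FALSE), and DESeq2 on the filtered genes.

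The tests were run on simulated data with the real means and library sizes and with edgeR's estimates of the dispersions. In these data 67, 67 and 66 genes were changed 2-fold, 4-fold and 16-fold (15422 genes in the step), and DESeq2 ran on the filtered genes. Changed genes were drawn only from those with a mean above 5 CPM, and all genes were simulated independently of one another. The edgeR test recovered 2.99% of the genes changed 2-fold, 59.7% of those changed 4-fold and 98.5% of those changed 16-fold, with 4 unchanged genes called. These shares do not carry over to every real gene: CXCL8 and IL36G, fitted at 26.6-fold and 53.8-fold, did not pass in edgeR's test (adjusted p = 0.165 and 0.0765). DESeq2 recovered 11.9%, 89.6% and 98.5%, with 66 unchanged genes called. In simulated lists of 25 independent genes changed 2-fold (15463 genes in the step), camera recovered 5 of 5 and called none of 31 unchanged lists with either correlation.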

Results

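Total RNA was sequenced from primary human bronchial epithelial cells, the cells that line the large airways, grown at an air-liquid interface so that they differentiate into basal, secretory and ciliated cells. The cells came from 3 healthy subjects and were exposed for 18 h to phosphate-buffered saline (PBS) or to 5 µg/ml of human neutrophil extracellular traps (NETs), the webs of DNA and granule proteins that neutrophils release. There were 3 PBS libraries and 3 NETs libraries. Total counts per library were 51290603, 53857740 and 62513276 for PBS replicates 1 to 3, and 71981670, 62063259 and 59779745 for NETs replicates 1 to 3. Of 25245 gene symbols, 21186 had a count in at least 1 library and 15730 were deep enough to be tested. The number of genes with a count was 18180 ± 108 (SD, n = 3) with PBS and 18750 ± 315 (SD, n = 3) with NETs (exact permutation test over 20 assignments, two-sided p = 0.1, the smallest p that 3 against 3 libraries allow, and 0.433 after Benjamini-Hochberg adjustment over 13 library measures).

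Libraries of one group were far from alike. The first principal component of log2 CPM (read counts scaled to the size of each library) took 44.4% of the variance and set NETs replicate 3 (score 111.6) and PBS replicate 2 (42.6) apart from the other libraries, which scored between -69.5 and -11.7. The second component, with 31.8% of the variance, scored -0.41 to 86.7 in the PBS libraries and -77.4 to -13.0 in the NETs libraries. Groups did not overlap in 17.4% of the tested genes, where 10% is the share that chance gives for 3 against 3, and the common biological coefficient of variation was 0.467.

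**Figure D1:**
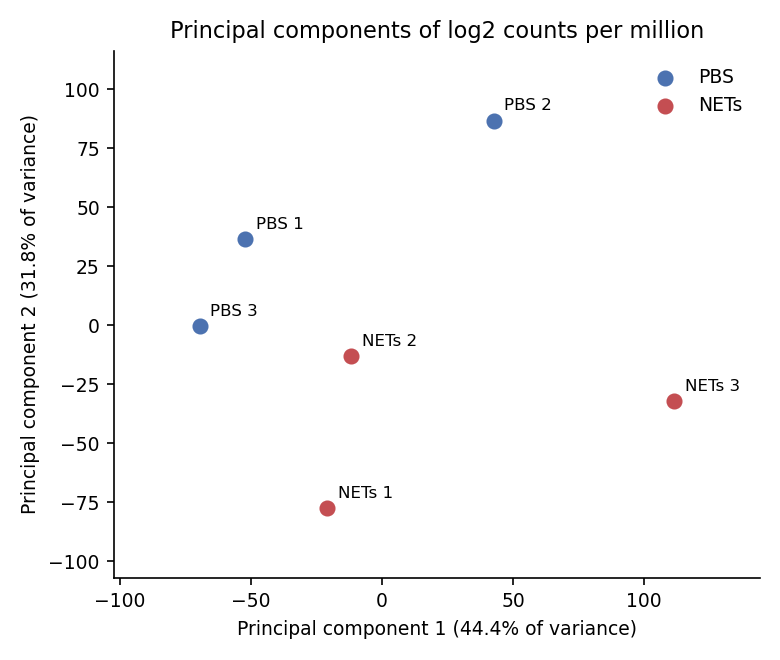
Scores of the 6 libraries on the first 2 principal components of log2 CPM (both axes in score units, with the share of variance in percent), 1 labelled point per library in the colour of its group. The 3 PBS libraries lie above the 3 NETs libraries on the second component, and NETs replicate 3 lies farthest to the right at 111.6.

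The comparison of NETs with PBS asks which genes of the airway epithelium respond to NETs, with interleukin-8 and the interleukin-1 family named in the title of the series. Only 6 genes passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test, and each of them kept the 3 NETs libraries apart from the 3 PBS libraries. SERPINB2, which encodes plasminogen activator inhibitor 2, rose from 28.7 ± 10.3 to 359 ± 31.9 CPM (SD, n = 3), a log2 fold change of 3.64 ± 0.36 (SE, adjusted p = 0.04). MMP9, a gelatinase that cuts basement membrane collagen, rose from 1.92 ± 1.54 to 93.9 ± 20.9 CPM (log2 fold change 5.61 ± 0.61, adjusted p = 0.04). SEMA7A, a membrane-anchored semaphorin, rose from 6.15 ± 1.11 to 240 ± 178 CPM, and SBSN, suprabasin of the cornifying epithelium, rose from 0.278 ± 0.246 to 25.5 ± 7.08 CPM (log2 fold changes 5.29 ± 0.59 and 6.49 ± 0.67, both with an adjusted p of 0.04). IL1R2, the decoy receptor that binds interleukin-1 without signalling, had 7 counts over the 3 PBS libraries and 1017 over the 3 NETs libraries (log2 fold change 7.01 ± 0.58, adjusted p = 0.0244). ID2, an inhibitor of basic helix-loop-helix transcription factors, fell from 56.0 ± 14.7 to 7.62 ± 1.60 CPM (log2 fold change -2.88 ± 0.32, adjusted p = 0.04). Leaving out 1 library moved some of these values: the log2 fold change of MMP9 was 6.50 without PBS replicate 1, the log2 fold change of SBSN was 7.51 without PBS replicate 3 and the log2 fold change of SEMA7A was 4.51 without NETs replicate 3.

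These 6 were among 1749 genes with an unadjusted p under 0.05, where evenly spread p-values would give about 786, with 1064 of them higher and 685 lower with NETs. Other splits of the 6 libraries, 3 against 3, gave 48 to 2176 such genes, so this number does not set the real groups apart. DESeq2's Wald test on the same counts called 559 genes (414 higher, 145 lower), the 6 among them. In the simulated data DESeq2 called 66 unchanged genes beside 8, 60 and 65 of those changed 2-fold, 4-fold and 16-fold. Its calls here and below may therefore hold more false ones than a false discovery rate of 0.05 allows. The simulation used edgeR's own dispersion estimates and ran DESeq2 on the filtered genes, while the 559 calls came from the unfiltered genes. How many of the 559 are false is thus not known. Removing any 1 library left few calls in edgeR's test: 1, 0 and 1 without PBS replicate 1, 2 or 3, and 0, 0 and 2 without NETs replicate 1, 2 or 3, with between 1115 and 2241 genes at an unadjusted p under 0.05. With the replicate number as a block edgeR called 0 genes and DESeq2 572, though the labels do not say that a number marks a subject. Same-numbered libraries' deviations from their group means correlated at only 0.086, -0.24 and -0.51. The block may thus join different subjects, so edgeR's 0 calls do not show what accounting for subjects would give.

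Interleukin-8 and the interleukin-1 genes had higher means with NETs, but of those fixed for report before the data were examined none passed over all genes tested. IL8 (now CXCL8), the main neutrophil chemoattractant of the airway, was at 72.2 ± 67.1 CPM with PBS and 1919 ± 2315 CPM with NETs (SD, n = 3). Each NETs library (798.1, 378.3 and 4581 CPM) was above each PBS library (37, 30.0 and 149.5 CPM), with a log2 fold change of 4.73 ± 1.11 and an adjusted p of 0.165. The log2 fold change of IL8 was 3.05 without NETs replicate 3 and 5.80 without PBS replicate 3. IL1RN, the interleukin-1 receptor antagonist, was at 43.6 ± 9.13 and 306 ± 73.9 CPM (log2 fold change 2.81 ± 0.33, adjusted p = 0.0539). IL1F9 (now IL36G), an epithelial ligand of the interleukin-36 receptor, was at 2.13 ± 1.87 and 115 ± 68.9 CPM (log2 fold change 5.75 ± 0.86, adjusted p = 0.0765). Its PBS values were uneven (0.46, 1.78 and 4.15 CPM), and its log2 fold change ran from 5.04 to 6.67 over 29 other settings. IL1B was at 1.07 ± 0.56 and 6.75 ± 5.51 CPM, and its NETs replicate 3 value of 1.39 CPM lay within the PBS range (adjusted p = 0.27). The groups overlapped for IL1A (33.3 ± 27.1 and 64.5 ± 38.3 CPM), for IL6 (0.795 ± 0.980 and 2.43 ± 3.32 CPM) and for CXCL1 (25.6 ± 21.96 and 45.6 ± 53.5 CPM), with adjusted p of 0.624, 0.777 and 0.797. Without NETs replicate 1 the log2 fold changes of IL6 and CXCL1 turned to -0.57 and -0.80. DESeq2 called IL8, IL1RN, IL1F9 and IL1B (adjusted p 2.21e-06, 8.31e-11, 8.87e-14 and 0.00929), and not IL1A, IL6 or CXCL1. Over 29 other settings the adjusted p ran from 2.38e-19 to 0.788 for IL8, from 1.69e-12 to 0.596 for IL1RN, from 1.09e-33 to 0.405 for IL1F9 and, over 28 settings, from 0.00929 to 1 for IL1B.

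**Figure D2:**
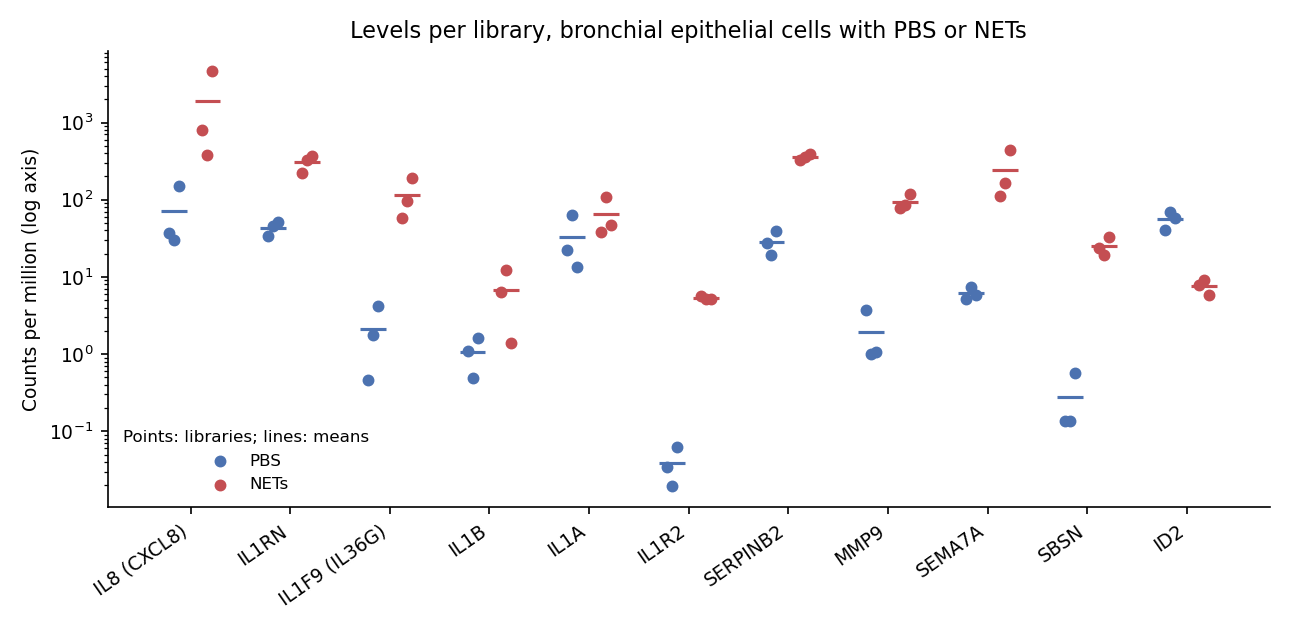
Normalised CPM on a log axis for 11 named genes, with 1 point per library, PBS in blue and NETs in red, and a line at each group's mean of 3 libraries. The 3 NETs libraries lie above the 3 PBS libraries for IL8, IL1RN, IL1F9, IL1R2, SERPINB2, MMP9, SEMA7A and SBSN and below them for ID2, while the groups overlap for IL1B and IL1A.

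Of 36 gene lists fixed before the data were examined, 32 had at least 5 tested members, and limma's camera called 18 of them with its preset correlation between genes of 0.01. Another of the 10 splits of the 6 libraries, 3 against 3, gave 20 called lists at that setting. The number of lists called there thus does not set the real groups apart. With the correlation estimated from the libraries only the list of interleukin-1 family ligands and receptors remained called (adjusted p = 0.0307). A call lost under that setting need not mean correlated genes. The interleukin-1 family list had an estimated correlation of -0.0187, below the preset 0.01, yet camera's unadjusted p rose from 5.17e-16 to 0.00096. In that list 14 of 16 tested members had positive log2 fold changes, with a median of 2.16 (camera adjusted p = 8.27e-15). IL1R2 was the 1 member that edgeR called over all genes, and 7 members were higher when adjusted over the list alone. DESeq2 called 7 members of this list higher over all genes. For every list below, counts over the list alone are edgeR's, and limma-voom called no member of a list in which edgeR called none. Next to IL1R2 and IL1RN in this list stood IL1F5 (now IL36RN), the antagonist of the interleukin-36 receptor, with 8 counts over the PBS libraries and 1064 over the NETs libraries (log2 fold change 7.01 ± 0.94, adjusted p = 0.0706). PBS replicate 3 held 6 of the 8 counts, and the log2 fold change of IL1F5 ran from 6.27 to 8.21 over 28 other settings. Over 17 other settings the adjusted p of this list ran from 4.3e-19 to 0.286, and the list was called in 16 of them.

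The lists of NF-kB targets and of neutrophil chemokines were both called higher by camera with its preset correlation, and neither call held with an estimated correlation. Among 27 tested NF-kB targets and feedback genes, 26 had positive log2 fold changes (median 1.12, camera adjusted p = 1.55e-13, and adjusted p = 0.109 with an estimated correlation). Over all genes edgeR called none of them (12 higher at an unadjusted p under 0.05) and DESeq2 called 6 higher, and 7 were higher when adjusted over the list alone. IL23A, a subunit of interleukin-23, was at 0.270 ± 0.168 CPM with PBS and 12.3 ± 6.11 CPM with NETs (log2 fold change 5.49 ± 0.74, adjusted p = 0.0706). PTGS2, the inducible cyclooxygenase, and IRAK2, a kinase of interleukin-1 receptor signalling, had log2 fold changes of 1.93 ± 0.35 and 2.32 ± 0.47 (adjusted p = 0.101 and 0.128). All 11 neutrophil-attracting chemokines and colony-stimulating factors had positive log2 fold changes (median 2.13, camera adjusted p = 4.77e-05, and adjusted p = 0.257 with an estimated correlation). Over that list alone 2 were higher, IL8 and CSF2 (the granulocyte-macrophage colony-stimulating factor), the latter with 700, 728 and 32 counts in NETs replicates 1 to 3 and 0, 0 and 8 in PBS replicates 1 to 3. The log2 fold change of CSF2 was 7.30 ± 1.51 (adjusted p = 0.13), and 11.77 without PBS replicate 3, where no PBS count was left and the fitted value is no bound. Over all genes edgeR called none of the list (3 higher at an unadjusted p under 0.05), and DESeq2 called 2 higher. PPBP, a platelet and neutrophil chemokine, stayed under 1 CPM in every library (log2 fold change 2.13 ± 0.79, adjusted p = 0.36).

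MMP9 and SERPINB2, both called over all genes, belong to the lists of proteases and of their inhibitors. In the list of matrix metalloproteases and plasminogen activation genes, 15 of 19 tested members had positive log2 fold changes (median 0.80, camera adjusted p = 2.48e-10, and adjusted p = 0.0888 with an estimated correlation). MMP9 was the 1 member edgeR called over all genes, DESeq2 called 6 higher, and 7 members were higher when adjusted over the list alone. ADAM8, a membrane-bound metalloprotease, was at 24.7 ± 8.13 CPM with PBS and 141 ± 27.2 CPM with NETs (adjusted p = 0.0735). PLAUR, the urokinase receptor, was at 41.5 ± 20.9 and 592 ± 311 CPM (log2 fold change 3.84 ± 0.57, adjusted p = 0.0765). Antiproteases were mixed, with 15 of 26 log2 fold changes positive (median 0.20, camera adjusted p = 0.00534, and adjusted p = 0.273 with an estimated correlation). Over that list alone 5 members were higher and 1 was lower, and DESeq2 called as many over all genes, where edgeR called SERPINB2. TIMP2 and TIMP3, both inhibitors of metalloproteases, went opposite ways, with log2 fold changes of 2.26 ± 0.37 and -2.42 ± 0.47 (adjusted p = 0.0977 and 0.114). The antiprotease call was lost without PBS replicate 1 (adjusted p = 0.0598) and without NETs replicate 2 (adjusted p = 0.0589).

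Genes of squamous cells and the cornified envelope, the protein shell of keratinising cells, were called higher with NETs (26 of 35 positive, median log2 fold change 1.94, camera adjusted p = 2.29e-15, and adjusted p = 0.257 with an estimated correlation). SBSN was the 1 member edgeR called over all genes, DESeq2 called 13 higher, and 12 members were higher when adjusted over the list alone. LCE3E, a late cornified envelope gene, had no count in the 3 PBS libraries and 158 in the 3 NETs libraries, at least 24.4-fold higher against a floor of 6 counts, or 3 fragments, over the group, and SCEL (sciellin) was at 42.7 ± 21.3 and 248 ± 53.8 CPM (adjusted p = 0.0944 and 0.0957). The list's median stayed at 1.94 with LCE3E set to its bound. Several of these genes belong to families of similar sequence, such as the small proline-rich and late cornified envelope genes, whose reads the counting could have shared.

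Basal cell markers moved apart from one another. Over the list of 21 tested markers alone, 8 were lower and 3 higher with NETs in edgeR's test, and the list was called lower (median log2 fold change -0.50, camera adjusted p = 0.00487, and adjusted p = 0.273 with an estimated correlation). No basal marker was called by edgeR over all genes (4 higher and 8 lower at an unadjusted p under 0.05), and DESeq2 called 3 higher and 6 lower. TP63, the transcription factor that maintains basal cells, was at 30.7 ± 3.54 CPM with PBS and 4.10 ± 1.95 CPM with NETs (log2 fold change -2.90 ± 0.43, adjusted p = 0.0765). DLK2 and SNAI2 had log2 fold changes of -3.82 ± 0.63 and -2.24 ± 0.40 (both with an adjusted p of 0.101). The markers LAMB3 and KRT17, chosen after their values were seen, went the other way, with log2 fold changes of 1.997 ± 0.48 and 1.80 ± 0.54 (adjusted p = 0.175 and 0.272 over all genes). The value of KRT17 is uncertain because it has pseudogenes of similar sequence.

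Junction, mucin and wound repair lists were called higher. Over all genes edgeR called no member of the 3 lists (8, 8 and 7 higher and 1, 0 and 3 lower at an unadjusted p under 0.05), and DESeq2 called 5, 5 and 3 higher and 1, 0 and 1 lower. Among 30 junction and barrier genes, 25 had positive log2 fold changes (median 0.69, camera adjusted p = 4.77e-05, and adjusted p = 0.273 with an estimated correlation), and over the list alone 6 were higher and 1 lower. CRB3 and JUP, of the apical polarity complex and the desmosome, had log2 fold changes of 1.27 ± 0.29 and 1.46 ± 0.38 (adjusted p = 0.156 and 0.207). In the list of mucins and the goblet cell programme, 19 of 26 log2 fold changes were positive (median 0.82, camera adjusted p = 4.77e-05, and adjusted p = 0.0888 with an estimated correlation), and 5 members were higher over the list alone. GALNT5, which starts O-linked glycosylation, CLCA4, a secreted protein of the calcium-activated chloride channel regulator family, and TFF1, a trefoil peptide, had log2 fold changes of 2.04 ± 0.35, 3.50 ± 0.66 and 1.62 ± 0.39 (adjusted p = 0.101, 0.106 and 0.178), with 2.40 for CLCA4 without NETs replicate 3. MUC5AC, the main secreted goblet cell mucin, was not matched to the table and not analysed here. Mesenchymal transition and wound repair genes were positive in 22 of 32 (median 0.60, camera adjusted p = 0.0413, and adjusted p = 0.537 with an estimated correlation), with 3 higher and 1 lower over the list alone, TGFB1 (log2 fold change 1.89 ± 0.42, adjusted p = 0.151) among the former and SNAI2 the latter. That call was lost without PBS replicate 2 (adjusted p = 0.303), NETs replicate 1 (0.133) or NETs replicate 2 (0.696).

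Stress and early response lists were also called higher. Over all genes edgeR called no member of either list (11 and 10 higher at an unadjusted p under 0.05), and DESeq2 called 4 higher in each. Of 27 genes of the unfolded protein and heat shock response, 18 had positive log2 fold changes (median 0.22, camera adjusted p = 0.00026, and adjusted p = 0.113 with an estimated correlation), and 4 were higher over the list alone. CHAC1, a glutathione-degrading enzyme induced by the unfolded protein response, had a log2 fold change of 2.07 ± 0.33 (adjusted p = 0.0944). The chaperone genes HSPA1A and HSPH1 had log2 fold changes of 2.37 ± 0.50 and 1.43 ± 0.30 (adjusted p = 0.131 and 0.134), with a log2 fold change of 1.72 for HSPA1A without NETs replicate 3 and its value uncertain because HSPA1B is a near-identical copy. Among 29 immediate early and AP-1 genes 20 were positive (median 0.48, camera adjusted p = 5.09e-05, and adjusted p = 0.441 with an estimated correlation), and over the list alone 3 were higher, SPRY4 and DUSP4, which restrain MAP kinase signalling, and FOSL1, an AP-1 subunit. Their log2 fold changes were 4.36 ± 0.93, 1.72 ± 0.40 and 3.58 ± 0.93 (adjusted p = 0.133, 0.165 and 0.207). FOSL1 was at 68.5 CPM in NETs replicate 3 and at 6.65 and 9.44 CPM in NETs replicates 1 and 2, and its log2 fold change was 1.78 without NETs replicate 3. Without PBS replicate 3 the adjusted p of that list was 0.0682.

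Interferon-stimulated genes and nucleic acid sensors were called higher too, and neither call held with an estimated correlation. Of 41 interferon-stimulated genes, 26 had positive log2 fold changes (median 0.39, camera adjusted p = 0.00569, and adjusted p = 0.441 with an estimated correlation), and in edgeR's test none passed over all genes or over the list alone (12 higher at an unadjusted p under 0.05). DESeq2 called 4 of the list higher over all genes. ISG20, IRF7 and IDO1 had log2 fold changes of 2.12 ± 0.53, 0.996 ± 0.29 and 2.63 ± 0.79 (adjusted p = 0.184, 0.26 and 0.268), with 1.30 for ISG20 without NETs replicate 3. The call was lost without PBS replicate 2 (adjusted p = 0.0712) and without NETs replicate 1 (adjusted p = 0.271). Among 19 genes of DNA and RNA sensing and Toll-like receptors, 13 were positive (median 0.24, camera adjusted p = 0.0452, and adjusted p = 0.257 with an estimated correlation). Over all genes edgeR called none of them (5 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 2 higher. TLR2 and MYD88, a receptor of bacterial lipoproteins and its adaptor, were higher over the list alone (log2 fold changes 2.16 ± 0.33 and 1.35 ± 0.28), and TLR4 had a log2 fold change of 1.31 ± 0.48 (adjusted p = 0.0776, 0.13 and 0.359 over all genes). Of the removals of 1 library, only that of NETs replicate 3 kept this call, with adjusted p of 0.0784, 0.0635 and 0.0548 without PBS replicate 1, 2 or 3 and of 0.213 and 0.133 without NETs replicate 1 or 2.

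The ciliated, cell cycle and sterol lists were called although no single member passed over the list alone, and none of these calls held with an estimated correlation. Among 37 ciliated cell markers, 34 had positive log2 fold changes (median 0.56, camera adjusted p = 0.00626, and adjusted p = 0.656 with an estimated correlation). In edgeR's test none passed over all genes, over the list alone or at an unadjusted p under 0.05, and DESeq2 called 0. C9orf24, SPAG6 and CCDC39 had log2 fold changes of 0.88 ± 0.46, 1.03 ± 0.57 and 1.23 ± 0.74 (adjusted p = 0.526, 0.556 and 0.592). In NETs replicates 1 to 3 SPAG6 was at 10.3, 17.3 and 39.1 CPM and CCDC39 at 0.78, 2.60 and 4.99 CPM. Their log2 fold changes ran from 0.064 to 1.76 over 29 other settings and from -0.077 to 2.09 over 28. The call of the ciliated list was lost without PBS replicate 3 (adjusted p = 0.579), NETs replicate 2 (0.0589) or NETs replicate 3 (0.499). Cell cycle genes were called lower, with 5 of 29 log2 fold changes positive (median -0.57, camera adjusted p = 0.00569, and adjusted p = 0.537 with an estimated correlation), and in edgeR's test no member passed over all genes or over the list alone (1 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 0. AURKA, a mitotic kinase, had a log2 fold change of -1.57 ± 0.51, and MCM5 and MCM4, subunits of the replicative helicase, had 0.87 ± 0.35 and -0.57 ± 0.33 (adjusted p = 0.304, 0.4 and 0.579). Without PBS replicate 2 or NETs replicate 1 the adjusted p of this list was 0.0545 and 0.201. Sterol synthesis genes were called lower too, with 2 of 24 log2 fold changes positive (median -0.77, camera adjusted p = 4.77e-05, and adjusted p = 0.443 with an estimated correlation), and in edgeR's test no single member passed (5 lower at an unadjusted p under 0.05), and DESeq2 called 0. EBP, SQLE and CYP51A1, enzymes of the pathway to cholesterol, had log2 fold changes of -0.97 ± 0.29, -1.53 ± 0.58 and -1.27 ± 0.51 (adjusted p = 0.272, 0.368 and 0.408). In PBS replicates 1 to 3 SQLE was at 153, 65.1 and 47.7 CPM and CYP51A1 at 256, 96.8 and 83.5 CPM. Over 29 other settings the log2 fold changes of SQLE and CYP51A1 ran from -2.35 to -0.54 and from -1.89 to -0.32.

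**Figure D3:**
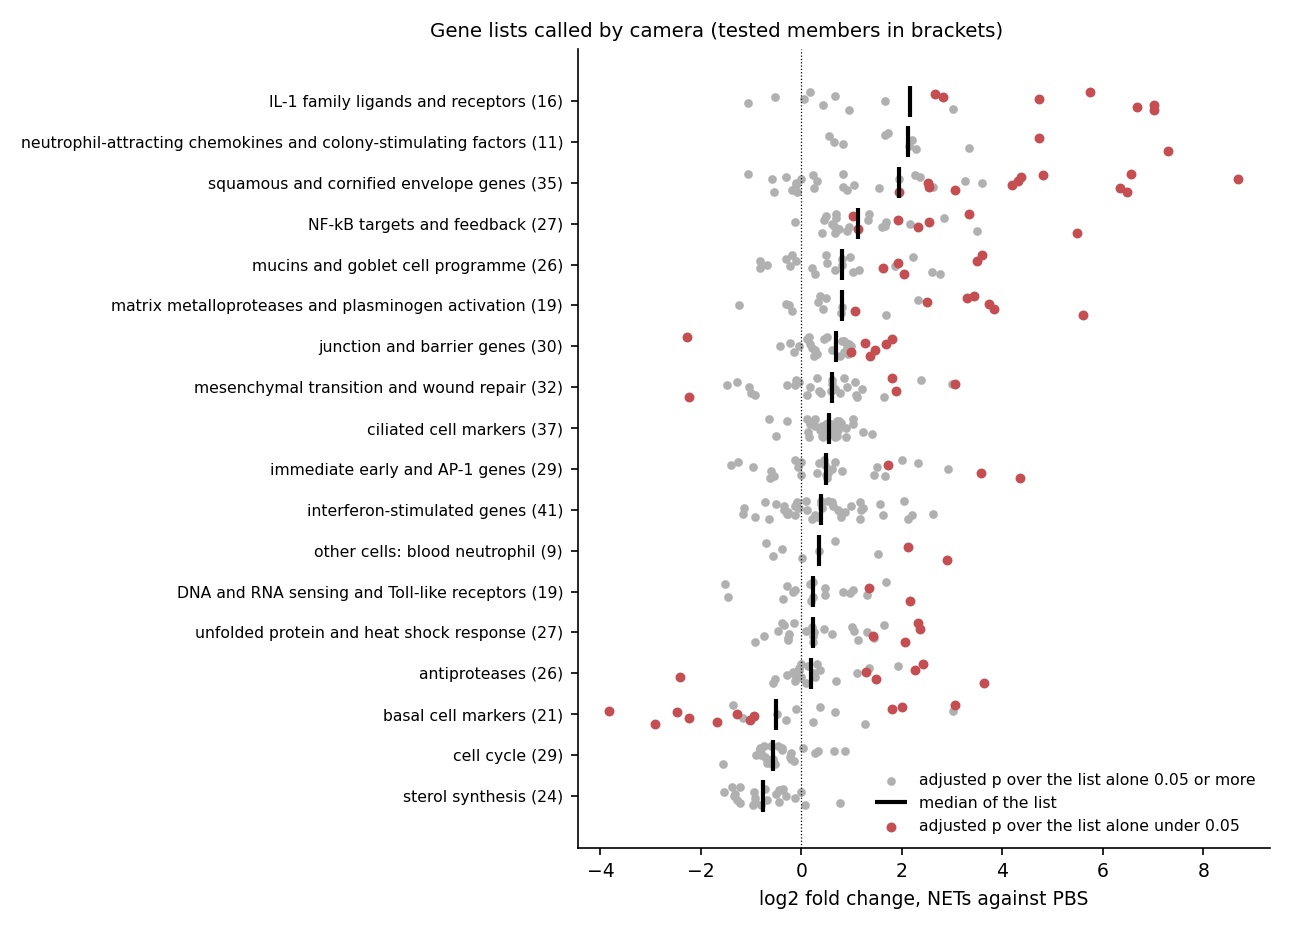
Log2 fold change with NETs against PBS for each tested member of the 18 lists that camera called, 1 point per gene, in red where the adjusted p over the list alone was under 0.05, with a black line at each list's median. Medians run from -0.77 for sterol synthesis to 2.16 for the interleukin-1 family, and the point of LCE3E in the cornified envelope list, fitted with no PBS count, is not a bound.

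The remaining epithelial lists were not called by camera, and edgeR called none of their members over all genes. DESeq2 called 3 antimicrobial genes, 1 club marker, 1 gene of glycolysis and 1 of the eicosanoid enzymes higher. It called 1 higher and 1 lower in the list of the epidermal growth factor receptor, 3 and 1 in ion transport, 1 and 2 among NRF2 targets, 2 and 2 in JAK-STAT feedback, and none in the other 4 lists. Adjusted p was 0.114 for antimicrobial and acute-phase proteins (1 of 26 higher over the list alone), 0.896 for inflammasome and pyroptosis genes, 0.878 for MHC class I presentation and 0.0646 for MHC class II presentation, where all 13 tested members had negative log2 fold changes and none passed over the list alone. It was 0.176 for ligands of the epidermal growth factor receptor and the receptor (1 higher and 1 lower of 11 over the list alone), 0.757 for club and other secretory markers, 0.407 for ionocyte and neuroendocrine markers and 0.47 for ion and fluid transport. NRF2 targets and oxidative stress genes gave 0.0613 (2 of 32 lower over the list alone), glycolysis and hypoxia 0.272, JAK-STAT and cytokine feedback 0.448, and prostaglandin and eicosanoid enzymes 0.407 (1 of 18 higher over the list alone). Median and mean log2 fold change had opposite signs for the inflammasome list (-0.12 and 0.03), for MHC class I presentation (-0.04 and 0.12) and for club markers (-0.04 and 0.10), which camera placed up, up and down.

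Markers of other cell types were checked because NETs are made from neutrophils. Summed over a list of 20 blood neutrophil markers, the level was 371 ± 285 CPM with PBS and 904 ± 627 CPM with NETs (SD, n = 3, exact permutation test, two-sided p = 0.2, adjusted p = 0.52 over 13 measures). Its 9 tested members were called higher (median log2 fold change 0.36, camera adjusted p = 0.0264, and adjusted p = 0.257 with an estimated correlation). That sum came mostly from KRT23, a keratin at 274 ± 294 and 794 ± 591 CPM (log2 fold change 1.53 ± 0.83, adjusted p = 0.544). KRT23 was at 131, 79.1 and 613 CPM in PBS replicates 1 to 3. TREM1, a receptor of myeloid cells, and GPR109B (now HCAR3) had log2 fold changes of 2.91 ± 0.50 and 2.12 ± 0.60 (adjusted p = 0.101 and 0.244), and both were higher over the list alone. Over 29 other settings the log2 fold changes of KRT23 and GPR109B ran from 0.42 to 3.33 and from 1.22 to 2.57. No blood neutrophil marker was called by edgeR over all genes (2 higher at an unadjusted p under 0.05), and DESeq2 called 2 higher. Fibroblast and endothelial lists were not called (adjusted p = 0.399 and 0.0613, with 1 of 7 endothelial members higher over the list alone). The lists of neutrophil granule genes, macrophages and monocytes, lymphocytes, and erythroid cells and platelets had 4, 4, 4 and 2 tested members and were not tested as lists. In edgeR's test 2 members were higher and 1 lower over the lymphocyte list alone, and no tested member of the other 3 lists passed. DESeq2, which also tested low counts, called 2 neutrophil granule genes higher, DEFA1 and DEFA1B (adjusted p = 0.00216 for both, named after their values were seen). These near-identical alpha-defensin genes had the same counts, 28, 2 and 54 in NETs replicates 1 to 3 and 0 in each PBS library, so their reads cannot be assigned to one of them. Most counts of the neutrophil granule list were of LTF (named after its values were seen), so its sum says little about the other granule genes. LTF had 12056, 461 and 45283 counts in PBS replicates 1 to 3 and 27833, 17621 and 206 in NETs replicates 1 to 3. With PBS and NETs the granule list summed to 350 ± 366 and 240 ± 194 CPM. Macrophage and monocyte genes summed to 112 ± 39.0 and 268 ± 182 CPM. The sums were 3.46 ± 1.19 and 3.44 ± 0.51 CPM for lymphocytes, and 0.960 ± 0.432 and 1.99 ± 0.774 CPM for erythroid cells and platelets. Exact permutation tests of these sums gave two-sided p of 0.8, 0.2, 1 and 0.1, the last being the smallest that 3 against 3 libraries allow (adjusted p = 0.945, 0.52, 1 and 0.433).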

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

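The GC offset, the halved counts, the removal of small structural RNAs, the removal of 2 libraries together, the newer edgeR fit and DESeq2 on filtered genes were chosen after seeing the data. The count of 6 genes (5 higher, 1 lower) rested on the tool and on every library. DESeq2 called 559 genes (414 higher, 145 lower), and 577 (420 and 157) on the filtered genes. Without a filter on low counts 84 were called (74 and 10), at a false discovery rate of 0.10 38 (35 and 3), with library totals only 11 (10 higher), and with the newer edgeR fit 9 (8 higher). A minimum fold of 1.5 left 3 (3 and 0), a GC offset left 2 (2 and 0), and removing PBS replicate 2 and NETs replicate 3 together gave 4 (0 lower), of which 2 were among the 6. With the GC offset only IL1R2 and SBSN still passed. The lowest log2 fold changes of MMP9 and SERPINB2 over 29 other settings were 5.11 and 3.35. Fewer genes or libraries, or another threshold, follow from the setting itself; for the others the cause was not tested. Removing 1 library, or 1 replicate number from both groups, gave 0 to 18 calls (0 to 18 higher, 0 lower) with 774 to 2341 genes at an unadjusted p under 0.05. Other scalings, limma-voom, robust dispersions, halved counts and removal of small structural RNAs gave 6 to 11 genes, all 6 among them, and a minimum of 5 CPM gave 6, 5 of them shared. Library totals moved the median log2 fold change of all genes by -0.11, and other scalings by less than 0.1.

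Replicate numbers were also tried as a block, since both groups carry the numbers 1 to 3. Same-numbered libraries' deviations from their group means correlated at 0.086, -0.24 and -0.51, and 0 of 3 PBS libraries correlated best with the NETs library of its own number, a hint from the data and not from the design. Each correlated best with a different NETs library, at 0.39 to 0.655. The numbers therefore were not taken to pair the libraries. If both groups came from the same 3 subjects, which the labels do not say library by library, the block by number may join different subjects, and the test without a block and the splits leave shared subjects out of account. With the replicate block edgeR called 0 genes (0 higher, 0 lower, 1232 at an unadjusted p under 0.05) and DESeq2 572 (387 and 185). With the block and without replicate 1, 2 or 3 edgeR called 8 (8 and 0), 114 (81 and 33) and 60 (47 and 13). Camera with the block called 17 lists, all among the 18.

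The 18 called lists fell to 1 with an estimated correlation, to 2 with fry and to 0 with the block and an estimated correlation. Other settings gave 14 to 23 lists, and no called list changed direction. Over 17 other settings the highest adjusted p of each list lay between 0.286 and 0.714.

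Among the 60 genes taken by the rule for named genes, 1487 values under other settings stayed on their side of the threshold in the same direction, 167 newly passed, 65 no longer passed and 7 changed sign. IL6 turned to -0.57 without NETs replicate 1, -0.83 without replicate 1 in both groups and -0.43 with the block and without replicate 2. CXCL1 turned to -0.80, -0.996 and, with the block and without replicate 1, -0.44. Without replicate 3 in both groups IL6 was at 3.87 and CXCL1 at 2.21. CCDC39 turned to -0.077 with the block and without replicate 3. At this spread between libraries, changes of about 2-fold were mostly not detectable.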

Other observations

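The genes named in this paragraph and the next were chosen after their values were seen. Several genes outside the lists had an adjusted p between 0.05 and 0.10 in edgeR's test, with all 3 NETs libraries on one side of all 3 PBS libraries. CD200, an immunoregulatory membrane glycoprotein, was at 0.0605 ± 0.0483 CPM with PBS and 3.01 ± 0.394 CPM with NETs (SD, n = 3, log2 fold change 5.62 ± 0.68, adjusted p = 0.0546). RND1 and TIAM1, regulators of the actin cytoskeleton, had log2 fold changes of 3.11 ± 0.40 and 3.26 ± 0.46 (adjusted p = 0.0706 and 0.0758). KIAA1199 (now CEMIP), which takes part in hyaluronan breakdown, was at 7.59 ± 2.32 and 92.7 ± 62.1 CPM, and the stress-inducible chaperone HSPA6 at 10.3 ± 3.55 and 87.6 ± 39.8 CPM (both with an adjusted p of 0.0765). DLL1, a Notch ligand, was at 23.8 ± 11.6 CPM with PBS and 2.53 ± 1.15 CPM with NETs (log2 fold change -3.23 ± 0.52, adjusted p = 0.0944).

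In lists that were not called, some members stood out when adjusted over the list alone. RNASE7, an antimicrobial ribonuclease, had a log2 fold change of 3.35 ± 0.43 (adjusted over the list alone 0.00118, and 0.0706 over all genes). Among NRF2 targets, AKR1B10 and GPX2 had log2 fold changes of -2.75 ± 0.60 and -2.67 ± 0.62 (adjusted over the list alone 0.037 for both, and 0.143 and 0.164 over all genes). EREG, a ligand of the epidermal growth factor receptor, and EGFR itself differed in sign, at 2.06 ± 0.41 and -1.02 ± 0.24 (adjusted over the list alone 0.00975 and 0.0142, and 0.117 and 0.166 over all genes).

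The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 6 called genes and the highest other split 0, so 1 of 10 splits gave as many, and the other splits had 48 to 2176 genes at an unadjusted p under 0.05 against 1749. For lists called by camera at the preset correlation the real split gave 18 and the highest other split 20, so 2 of 10 splits gave as many. That other split set PBS replicate 2 with NETs replicates 1 and 2. With an estimated correlation the real split gave 1 list and the highest other split 0.

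For the patterns below, the tests against the marker panels and all tests on the basal list were chosen after the values were seen. The first pattern is the higher level of the interleukin-1 family, NF-kB target and protease lists, whose 62 tested genes had a median log2 fold change of 1.10 and rose by 3675 CPM in sum. Of these genes edgeR called only IL1R2 and MMP9 over all genes. With an estimated correlation camera's calls of the NF-kB and protease lists were lost (adjusted p = 0.109 and 0.0888). RNA carried over from the neutrophils that made the NETs is argued against for the summed rise of these lists only. That sum is weighted to abundant genes and cannot tell for members at low levels, such as IL1R2 (0.0386 CPM with PBS, 5.36 CPM with NETs). PADI4 gave 207 of the 219 counts of a panel of 18 myeloid genes in PBS replicate 2. Without PADI4 that panel went from 0.491 CPM with PBS to 2.15 CPM with NETs. With PADI4 the panel, which holds FCGR3B and CSF3R that blood neutrophils express highly, rose by 0.728 CPM in sum, a ratio of 2e-04 to the rise of the lists. With 1 library left out and PADI4 kept, the panel's change ran from -0.233 CPM (without NETs replicate 3) to 1.86 CPM (without NETs replicate 2), with 1.83 CPM without PBS replicate 2, 0.00966 CPM without PBS replicate 1 and 0.347 CPM without PBS replicate 3, and the ratio was at most 5e-04. A GC bias between libraries and the normalization are argued against for the median only, which was 1.11 with a GC offset and 1.02 with library totals only. Over all genes, log2 fold changes hardly followed GC content (Spearman rho 0.0166), and library totals moved them by -0.11 in the median. With the GC offset edgeR still called IL1R2 over all genes, but no longer MMP9. A response of the epithelium to NETs stays open as a hypothesis, untested beyond these libraries.

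The second pattern is the split of basal markers, with TP63, DLK2 and SNAI2 lower and LAMB3 and KRT17 higher, the latter pair named after their values were seen. The smallest fall of TP63, DLK2 and SNAI2 was -2.24, and the other 18 tested markers had a median log2 fold change of -0.20 with an SD of 1.61. TP63, DLK2 and SNAI2 were taken as the members with the smallest p, so a smaller fall of the rest was nearly set by that choice. This comparison therefore cannot tell how far a lower share of basal cells accounts for their fall. Over the list alone 8 markers were lower and 3 higher, so the list did not fall as one. A loss of basal cells, regulation within the remaining cells, or both may contribute. With a GC offset the gap between the mean of LAMB3 and KRT17 and the mean of TP63, DLK2 and SNAI2 was 4.93, against 4.89 without it. This argues against a GC trend per library as the source of this gap only, since the genes were picked by their values. Over all genes log2 fold changes hardly followed GC content (Spearman rho 0.0166), so the offset had little room to move the gap. A change of basal cell state with NETs stays open and was not tested.

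The third pattern is a trace of leukocyte transcripts. FCGR3B had 53, 0 and 36 counts in NETs replicates 1 to 3 against 2, 0 and 0 in the PBS libraries, MNDA had 24, 0 and 24 and DEFA1, a neutrophil granule gene, 28, 2 and 54, against 0 in each PBS library. The myeloid panel's mean summed level was 1.39 times as high with NETs and 4.38 times without PADI4, which gave 207 of the 219 panel counts in PBS replicate 2. The lymphocyte panel's level was 2.37 times as high with NETs and 0.64 times without CD79A, which gave 66, 42 and 18 of its 78, 49 and 32 NETs counts. Leukocyte RNA that came with the NETs cannot be told apart from other sources with these counts, since each ratio depends on 1 gene, chosen after the values were seen, and NETs replicate 2 had 20 panel counts.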
